A study of Escherichia coli with 2 samples.

How the data were processed

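RNA from Escherichia coli K-12 MG1655, a laboratory wild-type strain, was sequenced as cDNA from LB cultures at early-exponential growth and at the transition to stationary phase. There were 2 libraries, 1 per growth phase, each with its own file. The labels' protocol mentions biological replicates of the cultures, but each growth phase was represented by 1 deposited library, and whether it pools cultures is not given in the sources used here.

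The deposited values were signal, the coverage of each base of the chromosome in whole numbers, without scaling to depth. Each file listed 4639675 positions in order and carried no header, strand or gene name. The aligner, the treatment of reads with several matches, the genome build and any filter are not given in the sources used here. That the authors' values are coverage and not read starts was tested on the files. Of the stretches at value 1 bounded by zeros, 97.3% in the early-exponential library and 97.5% in the transition library were exactly 36 bases long. One read therefore added 1 to each of 36 bases, and sums of coverage were divided by 36 to give read equivalents. Because the values carry no strand, overlapping or antisense transcripts cannot be told apart.

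The design fixed before the data were examined asked for values per gene, with 40 lists of named genes. The gene table at hand belongs to the assembly ASM584v2, and its gene positions run past the last position of the files, so its coordinates are of another build. No gene was placed on the files' coordinates, and no gene list was evaluated here. The fallback fixed in the same design was used instead. The chromosome was divided into 4640 windows of 1000 bases, the last of 675 bases, and all positions are those of the files, counted from 1.

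For each window, read equivalents were summed in each library. The planned scaling to the total over protein-coding genes could not be computed without gene positions. The main scaling was the median of the log2 ratios (0.5 added to each value) over windows with at least 50 read equivalents in both libraries together, a method planned as an alternative. It was made the main one after the windows had been examined, because 10 windows held 60.5% of the transition reads. The median window had a transition-to-early ratio of 0.665, and folds are given relative to it. Windows at least 4-fold higher or lower, with at least 50 read equivalents over both libraries, were counted. With 1 library per group there was no residual spread between libraries, so no test was made and no p-value is given. Intervals of folds are exact conditional binomial (Clopper-Pearson) 95% intervals. They cover counting error only, and reads copied by PCR are not independent molecules. No window that was counted had under 1 read equivalent in a library.

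The windows named were chosen by the fixed rule. They are the 15 with the highest and the 15 with the lowest fold, ranked by the bound of the interval nearest to 1, with at most 2 from a run of adjacent windows called in the same direction, and the 10 with the most reads in each library. The parts of the rule that name genes could not be applied. Around the highest base of each named window, a footprint was taken as the stretch whose coverage stayed at or above 20% of that base, in the library where the window held the larger share of reads. Runs were adjacent windows past a fold threshold, compared with 1000 random placements of as many windows. Medians were taken in 23 bins of 200 kb, the last extended to the end, with 2000 resamplings of the windows of a bin. A cosine of 1 period around the chromosome was fitted to the log2 folds and compared with 10000 shuffles of 20-kb blocks.

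The alternatives were scaling to the total over all bases, a trimmed mean of log ratios (30% of ratios and 5% of levels trimmed at each end), other minimums, the median base in place of the mean, capped base values, each part of a window on either side of its middle, windows rich in zeros left out, and other fold thresholds. Other window widths, shifted windows and removal of the fitted wave were added after the data were seen. Leaving out bases shared between genes, and genes with near-identical copies, was not run because no genes were placed.

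The procedure was tested on simulated libraries drawn from the real windows and totals. Of 91 windows changed 8-fold, 100.0% were recovered as at least 4-fold, and of 92 windows changed 5.66-fold, 97.8% were. Of 3604 unchanged windows, 0 were called, and the interval held no change in 95.0% of them. A simulated wave of amplitude 0.4 was fitted as 0.394, and with none put in the amplitude was 0.0049. These simulations hold counting error only. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.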

Results

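Transcript coverage was compared between early-exponential growth and the transition to stationary phase in LB-grown E. coli K-12 MG1655, with 1 library for each. The early-exponential library held 2153941 read equivalents of 36 bases and the transition library 2779375. Mean coverage per base was 16.7 in the early-exponential and 21.6 in the transition library, while the median base was covered by 2 reads and by 1 read, respectively. No read lay over 24.3% of bases in the early-exponential library and over 32.1% in the transition library. Shares of reads are shares of the deposited coverage, and any reads removed before it cannot be counted. An uncovered base therefore need not lack transcripts. The precision was set by counting error within windows, and the spread between cultures could not be measured. Differences therefore describe these 2 libraries and have no replicate check. All folds, unless said to be by share, from the median base or from 1 side of a window, are relative to the median window. Its transition-to-early ratio of read equivalents was 0.665. A transition-to-early fold on this scale is 1.94 times the ratio of a region's shares of the 2 libraries. Folds from the median base were scaled to the median log2 ratio of that measure, -0.583. Those from the bases before and past a window's middle were scaled likewise, to -0.572 and -0.594, against -0.588 in the main scaling.

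A few short regions held a large share of the reads, and a larger one at the transition. The 10 most covered windows of 1000 bases held 33.5% of the early-exponential reads and 60.5% of the transition reads, and 6 windows were among the 10 in both libraries. A single window, 2922001 to 2923000, held 29.2% of the transition library (exact binomial 95% interval 29.1% to 29.2%) against 4.57% of the early-exponential library. The densest part of this region, a footprint of 149 bases from 2922247 to 2922395, reached a coverage of 291338 reads at its highest base in the transition library and 33403 at the same base in the early-exponential library. Relative to the median window, the region's window was 12.4-fold higher at the transition (95% counting interval 12.3 to 12.5), and by share it was 6.39-fold higher. Its median base, which leaves out the dense part, gave a log2 fold of -0.74.

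The most covered region of the early-exponential library lay in the window 2753001 to 2754000, with 187160.2 read equivalents, or 8.69% of that library. The transition library held 163998.7 read equivalents there, 5.90% of its reads. Its fold relative to the median window was 1.32 (1.31 to 1.33), but by share of all reads it was lower at the transition. Its footprint of 130 bases, from 2753803 to 2753932, held 6.80% of early-exponential and 4.35% of transition reads. Relative to the median window that footprint was 1.24-fold higher (1.23 to 1.25), so the direction of the dense part depended on the scaling and was not settled. The window's median base, 18 and 7 reads, gave a log2 fold of -0.78 and the bases before its middle -1.04. Both values leave out the dense part. The window 3054001 to 3055000, with a footprint of 124 bases from 3054049 to 3054172, held 5.24% of the early-exponential and 11.4% of the transition reads. It was 4.23-fold higher (4.20 to 4.26) relative to the median window and 2.18-fold higher by share, while its median base gave a log2 fold of -0.87. A footprint of 95 bases from 475685 to 475779 held 2.85% and 3.08% of the reads. Its window was 2.09-fold higher (2.07 to 2.11) relative to the median window, with a log2 fold of 0.11 by share of all reads. The window 4049001 to 4050000 held 0.878% and 1.78% of the reads. It was 3.94-fold higher (3.87 to 4.00) relative to the median window and 2.03-fold higher by share.

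Of the other abundant windows, 4 held fewer reads at the transition relative to the median window, in 3 of them on only 1 side of the middle. The adjoining windows 3717001 to 3718000 and 3718001 to 3719000 held 2.27% and 1.94% of early-exponential reads and 0.423% and 0.372% of transition reads. They were 2.76-fold (2.70 to 2.82) and 2.68-fold (2.63 to 2.74) lower. A footprint from 3717922 to 3718029 crosses their common edge, so these windows share 1 dense part and are not separate regions. That footprint held 3.10% of early-exponential and 0.609% of transition reads and was 2.63-fold lower (2.58 to 2.67). The window 3268001 to 3269000 was 1.60-fold lower (1.57 to 1.62), and the window 2735001 to 2736000 was 1.56-fold lower (1.53 to 1.59), with log2 folds of -1.63 and -1.60 by share of all reads. The median base had the same coverage in both libraries in 3 of these 4 windows, at 2, 1 and 13 reads in 3717001, 3718001 and 2735001, and was 4 and 3 reads in 3268001, a log2 fold of 0.17. The bases before the middle of 3717001 gave a log2 fold of 1.08, and those past the middle of 3718001 and 2735001 gave 0.40 and 1.57. At 3717001 and 3718001 these bases lie away from the shared footprint. Both sides of 3268001 were lower, with log2 folds of -0.55 before its middle and -0.85 past it. The windows 2816001 to 2817000 and 1755001 to 1756000 had log2 folds of 0.97 and 0.58 relative to the median window, and of 0.01 and -0.37 by share of all reads. Their median bases gave log2 folds of -1.84 and 2.08, and the bases before the middle of each window -3.24 and -0.10, so neither window had a settled direction. The footprint from 2816599 to 2816656, past the middle of its window, was 2.10-fold higher (2.08 to 2.13) relative to the median window and 1.09-fold higher by share. The densest 36 bases held 77.3% and 57.0% of the early-exponential coverage of the footprints at 3717923 and 2735157, and 73.9% of the transition coverage of that at 2816599. In the longer footprint from 3717922 to 3718029 they held 47.8% of the early-exponential coverage.

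**Figure D1:**
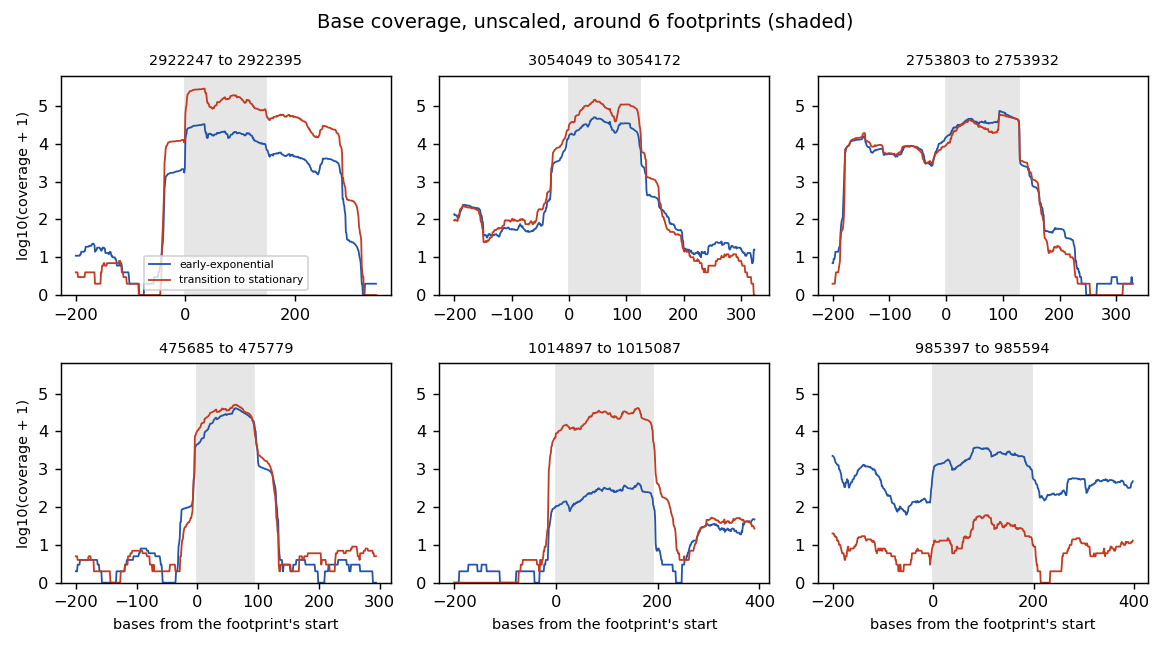
Coverage of each base, unscaled, on a log10 axis after adding 1, for 5 of the most covered footprints of the transition library and for the footprint from 985397 to 985594, with 200 bases on each side. Lines are the 2 libraries and shading marks the footprint; coverage at the footprint from 2922247 to 2922395 is higher in the transition library throughout, while at 985397 to 985594 it is lower.

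Across the chromosome, 3798 windows held at least 50 read equivalents over both libraries. Of these, 253 were at least 4-fold higher at the transition and 167 at least 4-fold lower, while 2703 (71.2%) lay within 2-fold of the median window. The excess of higher windows lay mostly among the least covered of them. With 50 to 200 read equivalents over both libraries, 84 windows were higher and 11 lower. With 200 to 1000 the counts were 101 and 97, and with 1000 or more they were 68 and 59. At least 16-fold differences were found in 50 windows that were higher and in 57 that were lower. The 253 higher windows held 55.5% of the transition reads and 11.4% of the early-exponential reads. The 167 lower windows held 0.404% and 9.92%, respectively. Most of the share of the higher windows lay in 2922001 and 3054001. These held 29.2% and 11.4% of the transition reads, and 4.57% and 5.24% of the early-exponential reads. Scaling to all reads instead moved the median window to a log2 fold of -0.96 and gave 131 higher and 446 lower windows, 22.7% of the calls being higher against 60.2% in the main scaling. Taking the median base of each window instead of its mean gave 224 higher and 375 lower windows, 37.4% higher, a measure that leaves out short covered stretches.

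**Figure D2:**
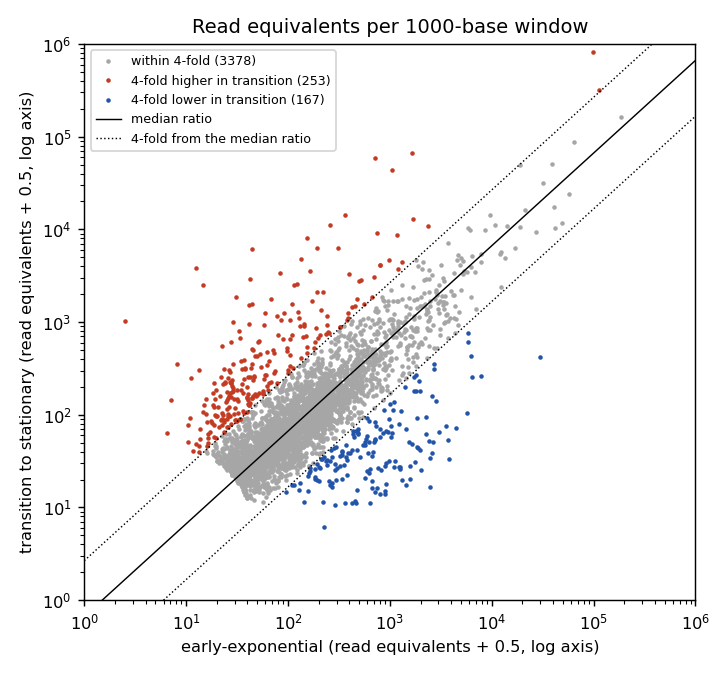
Each point is 1 window of 1000 bases with at least 50 read equivalents over both libraries; both axes are logarithmic and give read equivalents plus 0.5. The solid line is the median ratio and the dotted lines lie 4-fold from it, with 253 windows above and 167 below them.

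The windows with the highest folds ranged from 2 to 1632 read equivalents in early-exponential growth. Of the 15 windows with the highest folds, 8 held fewer early-exponential read equivalents than the median window, which held 109. The window 1567001 to 1568000 held 12 read equivalents in the early-exponential library and 3841 at the transition, 462-fold higher (275 to 932). Nearby, the window 1569001 to 1570000 went from 2 to 1032 read equivalents, 621-fold, with an interval of 214 to 6411 because of the low early count. A footprint of 191 bases from 1014897 to 1015087 held 0.0586% of early-exponential and 4.41% of transition reads. It was 146-fold higher (138 to 154) relative to the median window and 75.3-fold higher by share. The 2 windows that share this footprint were 123-fold (115 to 133) and 61.5-fold (58.6 to 64.7) higher. Their parts away from it had log2 folds of 0.34 before the middle of 1014001 and -0.99 past the middle of 1015001, whose median base gave -0.049. A footprint of 74 bases from 4276005 to 4276078 lay in a window 77.5-fold higher (66.4 to 92.0), with a log2 fold of 0.36 past the window's middle. Its densest 36 bases, the length of a read, held 65.1% of its coverage at the transition.

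Single windows at 877001 to 878000, 4257001 to 4258000 and 3464001 to 3465000 were 64.7-fold (57.3 to 73.6), 57.9-fold (52.2 to 64.4) and 49.5-fold (42.9 to 57.5) higher. The median base gave log2 folds of 1.17 at 877001 and -0.15 at 4257001, and the bases past the middle of 4257001 gave -0.66. The footprint of 58 bases from 4257217 to 4257274 had 80.9% of its transition coverage in its densest 36 bases. The windows 4216001 to 4217000 and 4213001 to 4214000 belonged to 1 run of adjacent higher windows and were 61.6-fold (49.8 to 78.0) and 54.1-fold (45.6 to 64.7) higher. The windows 3303001 to 3304000, 1067001 to 1068000 and 511001 to 512000 were 55.3-fold (40.8 to 77.7), 53.5-fold (39.8 to 74.2) and 52.5-fold (37.3 to 82.1) higher. Footprints in the 15 windows with the highest folds were 58 to 292 bases long, with a median of 144, and those in the 15 with the lowest folds 81 to 383, with a median of 209.

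The windows named for the lowest folds were well covered in early-exponential growth. Ranking by the interval bound favours such windows, so this follows in part from the rule. The window 2824001 to 2825000 held 2478 read equivalents in the early-exponential library and 16.3 at the transition, 98.2-fold lower (63.3 to 181). The window 2826001 to 2827000, in the same run, was 53.1-fold lower (35.9 to 82.4). The neighbouring windows 1130001 to 1131000 and 1131001 to 1132000 were 77.1-fold (54.8 to 112) and 46.5-fold (35.7 to 62.6) lower. The most covered of these windows, 985001 to 986000, went from 29649 to 419 read equivalents, or from 1.38% to 0.0151% of the reads. It was 47.0-fold lower (42.8 to 52.0) relative to the median window and 91.2-fold lower by share.

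The windows 4588001 to 4589000 and 4587001 to 4588000 were 55.3-fold (35.0 to 96.7) and 37.9-fold (26.7 to 56.2) lower. The windows 2012001 to 2013000 and 2014001 to 2015000 were 50.8-fold (33.5 to 85.3) and 42.9-fold (25.5 to 79.0) lower. The windows 4464001 to 4465000 and 4463001 to 4464000 were 48.2-fold (34.7 to 70.4) and 44.5-fold (32.7 to 63.7) lower. At 4464001 the median base gave a log2 fold of -0.40 and the bases past the middle -0.075, and the densest 36 bases of its footprint held 58.9% of the early-exponential coverage there. That footprint lies inside the longer one of 4463001, from 4463909 to 4464221, where the densest 36 bases held 32.2%. The windows 3263001 to 3264000 and 3264001 to 3265000 were 41.2-fold (32.7 to 53.0) and 36.5-fold (30.1 to 44.9) lower. The window 4245001 to 4246000 was 38.0-fold lower (26.7 to 59.4), and 3371001 to 3372000 was 34.7-fold lower (26.4 to 46.9).

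Windows past the 4-fold threshold lay next to each other far more often than random placement gave. The lower windows formed 22 runs of 3 or more adjacent windows, which held 122 of the 167, against a mean of 0.258 such runs in random placements. The higher windows formed 23 such runs holding 118 of the 253, against a mean of 0.904. Neighbouring windows can share a transcript, so windows are not independent.

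The longest higher run covered 15000 bases from 3651001 to 3666000. Its read equivalents went from 1692 to 58753, 52.2-fold (49.7 to 54.8) relative to the median window, and its share from 0.0785% to 2.11% of the reads. Within it, the window 3654001 to 3655000 held 43205 read equivalents at the transition and was 61.5-fold higher (57.9 to 65.5), the window 3656001 to 3657000 was 208-fold higher (156 to 289), and the window 3652001 to 3653000 was 102-fold higher (76.2 to 144). Further runs at least 4-fold higher lay at 1031001 to 1042000, 17.5-fold (15.4 to 19.96), at 1596001 to 1606000, 7.84-fold (6.84 to 9.09), at 3014001 to 3022000, 8.59-fold (7.49 to 9.88), and at 4213001 to 4219000, 38.7-fold (35.4 to 42.6).

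The longest runs at least 4-fold lower each covered 12000 bases. The run from 2010001 to 2022000 went from 9714 to 201.5 read equivalents, 32.0-fold lower (27.8 to 37.0), and the run from 1128001 to 1140000 from 21257 to 601.6, 23.5-fold lower (21.7 to 25.5). A run of 9000 bases from 3257001 to 3266000 was 26.0-fold lower (23.8 to 28.6), and one of 8000 bases from 4241001 to 4249000 was 15.3-fold lower (14.03 to 16.7). Between 1960001 and 1975000, 15 adjacent windows were each at least 2-fold lower, 6.72-fold over the whole stretch (6.23 to 7.27). The run from 2823001 to 2829000 was 29.3-fold lower (25.3 to 34.3).

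Folds also differed by position on the scale of the whole chromosome. The median log2 fold of 200-kb bins was highest from 1400001 to 1600000, at 0.83 (95% resampling interval 0.72 to 0.96, 127 windows), and next from 1600001 to 1800000, at 0.50 (0.32 to 0.73, 165 windows). It was lowest from 3200001 to 3400000, at -0.26 (-0.46 to -0.15, 180 windows). In the 4 bins from 3800001 to 4639675 it lay between -0.20 and -0.16. The resampling drew single windows, although neighbours can share a transcript, so these intervals are likely too narrow. They do not cover the spread between cultures. Without the windows past 4-fold, the median from 1400001 to 1600000 was 0.75. The share of windows at least 4-fold higher did not follow the same order. It was 18.5% from 1000001 to 1200000, 16.5% from 1400001 to 1600000 and 17.0% from 1600001 to 1800000, but also 13.7% from 3600001 to 3800000 and 11.5% from 3000001 to 3200000, and it was 0.559% from 3800001 to 4000000.

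**Figure D3:**
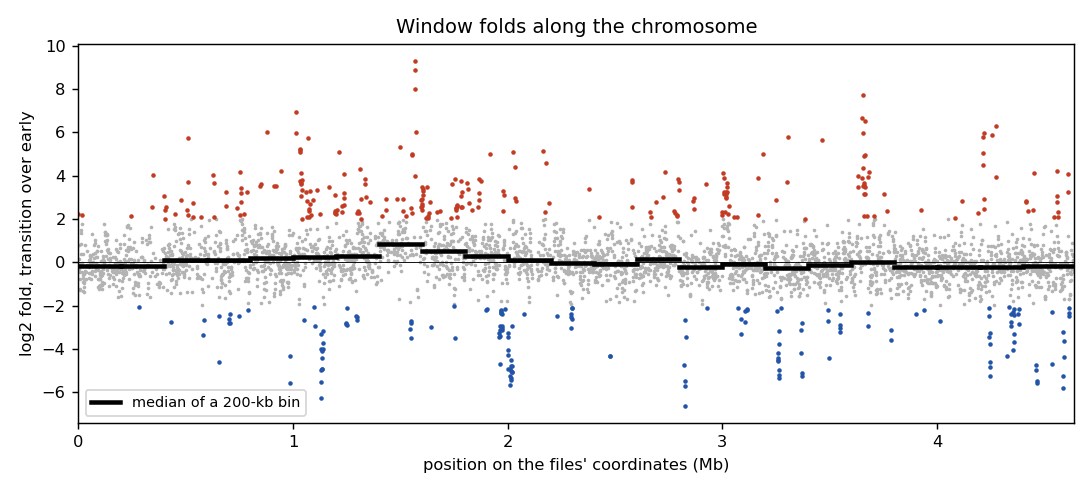
Log2 fold of each window (points) along the files' coordinates in Mb, with windows at least 4-fold higher in red and at least 4-fold lower in blue; black bars are medians of 200-kb bins. The bar from 1.4 to 1.6 Mb is the highest, at 0.83, and the bars past 3.8 Mb lie below 0.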

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

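No replicate could be left out, because each growth phase had 1 library, and the alternatives that need gene positions were not run. Window widths, shifted windows and removal of the wave were chosen after the data were seen. Scaling to all reads gave 131 windows at least 4-fold higher and 446 lower, and a median log2 fold of -0.96; the most covered window alone moved the ratio of library totals from 1.29 to 0.958. The median log2 fold was 0.019 with a minimum of 1 read equivalent and -0.089 with a minimum of 200, sets that hold more and fewer windows. The median base in place of the mean gave 375 lower windows; the fold threshold of 2 gave 625 higher and 470 lower; windows of 500 bases gave 516 and 334, and windows of 2000 bases 128 and 86, since their number differs. The other alternatives kept both counts within 1.5 times the main ones. Among them, the minimum of 200 gave 169 higher and 156 lower windows, 52.0% of the calls being higher against 60.2% in the main setting. Of 297 alternative values of the 33 named windows past 4-fold, 283 stayed past 4-fold in the same direction, 6 reversed and 8 fell below 4-fold. The 283 include every value from the other minimums and from leaving out windows rich in zeros. Those settings only choose windows and cannot move a named window's fold, so the 283 overstate how well the folds held. With the median base, the log2 fold became -0.049 at 1015001 to 1016000, -0.74 at 2922001 to 2923000, -0.87 at 3054001 to 3055000 and -0.15 at 4257001 to 4258000; with the window's bases past its middle alone it became -0.99 at 1015001 and -0.66 at 4257001. In 2 of the 8, at 1014001 and 4276001, the median base was equal in both libraries, so that its log2 fold of 0.58 is the scaling alone. The others were log2 1.12 at 3054001 with scaling to all reads, 1.17 at 877001 and -0.40 at 4464001 with the median base, and 0.34 at 1014001, 0.36 at 4276001 and -0.075 at 4464001 with one side of the window alone. Of 81 alternative values of the 9 named windows within 4-fold, 11 turned direction, not counting 3 with equal median bases. The 81 also include the settings that cannot move a named window's fold. Depth limits windows below 50 read equivalents, of which there were 842.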

Other observations

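All tests in this part except those of dosage, extreme windows and amplification were chosen after the result was seen. Both libraries had no coverage at the same 13.9% of bases, and 56 uncovered stretches of 500 bases or more made up 51465 bases. All 23 such stretches of 1000 bases or more were between 1000 and 1400 bases long, the longest running from 380450 to 381804. The concentration of coverage within windows was also measured. Among windows with 200 to 1000 read equivalents in the transition library, the densest 100 bases held a median of 32.1% of the coverage in the 90 higher windows and 35.2% in the 500 within 4-fold. In the early-exponential library these medians were 24.95% in the 95 lower windows (quartiles 21.7% and 33.1%) and 30.1% in the 825 within 4-fold (24.2% and 41.1%), with no test of the difference.

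The ratio of the libraries followed a wave around the chromosome: a fitted cosine had an amplitude of 0.29 in log2, a 1.49-fold difference between its ends, against 0.18 at the 95th percentile of shuffled blocks, and 3 of 10000 shuffles were as large. It did not rest on a few extreme windows, since the amplitude was 0.24 without those past 4-fold and 0.23 without the bin with the highest median. Its maximum lay at 1454429 and its minimum at 3774267. Fitted to the log2 levels of the early-exponential library alone, the amplitude was 0.22, with the maximum at 3759692, and 133 of 10000 shuffles were as large. For the transition library it was 0.071, and 5629 were as large. The wave may reflect gene dosage, since fast-growing cells carry more copies of regions near the replication origin. Its phase was not tested because the origin's place on these coordinates was not used. Regional differences in transcription stay open too. Carry-over of genomic DNA would bear the same dosage and stays open: among windows with 1000 or more read equivalents the amplitude was 0.061, and its component along the phase of the least covered windows was 0.058, with a resampling interval of -0.55 to 0.64 that is too wide to decide. Among those with 200 to 1000 this component was 0.25 (0.024 to 0.45), against 0.025 expected if only reads at the floor level carried it. Among those with 50 to 200 it was 0.36 (0.27 to 0.44) against 0.086, but these lie near the floor themselves, with a median of 36.5% of reads at its level. In the 798 least covered windows, which set the phase, the component was 0.24 (0.15 to 0.32). That interval overlaps the one for 50 to 200.

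The region from 2922247 to 2922395 took 23.7% of the transition reads. Amplification of a few molecules would stack reads on a single position, but its densest 36 bases held 39.4% of its coverage. Reads stacked on 1 position can account for no more than that share, while amplification at several positions was not tested. The base profiles of the libraries correlated at 0.93 across its bases. The share in 36 bases was larger at some other footprints. Of 41 in named windows, 6 were 58 to 86 bases long and held from 57.0% to 80.9% of their coverage in 36 bases. These values are for the library with the larger share of reads. The 41 are not all separate. Those at 3717923 and 4464140 lie inside longer footprints of adjoining windows, from 3717922 to 3718029 and from 4463909 to 4464221. In the longer footprints the densest 36 bases held 47.8% and 32.2% of the early-exponential coverage, so the share depended on which window set the footprint. The profile correlations of these 6 ran from 0.68 to 0.99, so the correlation does not set the region at 2922247 apart from them. A short length itself raises the share in 36 bases, so amplification stays open at these 6 as well. They start at 2735157, 2816599, 3717923, 4257217, 4276005 and 4464140. A bias of the library preparation for this transcript that differs between the libraries was not tested, and a difference between growth phases stays a hypothesis that 1 library each cannot settle.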
